A study of Caenorhabditis nigoni and Caenorhabditis briggsae with 14 samples.

How the data were processed

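Libraries were made from total RNA of whole worms with a stranded TruSeq mRNA kit, per the labels. The male libraries were made from 300 ng of RNA and sequenced as paired reads of 150 nt on a MiSeq. The amount of RNA and the read length of the female libraries are not given in the sources used here. Each library pooled 300 young adult animals. Introgression males were progeny of fertile introgression-carrying females and JU1421 males and were picked by a green fluorescent marker driven by a pharyngeal myosin promoter. The submitters' processing notes name Trimmomatic and edgeR, without versions. The aligner, the counting program, the genome build, the gene and repeat annotation and the strand setting are not given in the sources used here.

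The authors deposited raw counts per gene for 14 libraries and raw counts per repeat family for the 12 male libraries, per the file headers. Values are whole numbers. Genes are listed by WormBase identifier, 23439 in all, and repeat families by number, 361 with the prefix cb and 559 with the prefix c_sp9. The files do not pair identifiers with gene names or positions, and no reference was used here, so no gene is named and none is placed on a chromosome. For that reason 3 planned parts were not run: gene lists by function, the gene of the marker promoter, and genes inside the introgressed X intervals. Genes that share reads with near-identical copies, or that overlap on opposite strands, cannot be told from their counts alone, and how reads shared between a gene and a repeat were assigned is likewise open.

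Groups were taken from the strain and sex in the labels. Replicate libraries of a group differed by far more than sampling noise (chi-square per degree of freedom 7.26 to 26.5), so none was treated as a duplicate. Genes were kept by filterByExpr of edgeR with its minimum count of 10, which left 13289 genes. Counts of the 12 male libraries were scaled by TMM and fitted together with 1 coefficient per strain, and strains were compared by the quasi-likelihood F test of edgeR with robust fitting. Genes with a Benjamini-Hochberg adjusted p below 0.05 are called higher or lower. CPM of single genes use TMM-scaled library sizes. Repeat families with at least 10 counts over the 12 libraries, 696 in all, were tested the same way with the library sizes and factors of the gene counts. A gene lies outside both parents when it passes against JU1421 and against AF16 in the same direction.

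Male-biased and female-biased genes were taken in each parent from 3 male libraries and 1 female library, at a ratio of 4 or more with a prior count of 2, at least 5 CPM in the higher sex, and every male library on that side. The AF16 sets were tested with camera of limma on log2 CPM, with a preset correlation of 0.01 and again with an estimated one, adjusted over the 4 planned tests. Shares of counts were compared by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 against 3 libraries. Fitted medians of the sets barely depend on genes without a count in one strain: with those held at the bound set by 3 counts over the group, the male-biased medians were -1.47 in ZZY10307 and -1.19 in ZZY10330.

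Genes named in the text are, per comparison, at most 2 each way with the largest fold among called genes with at least 10 CPM in the higher group and no overlap between the libraries. Repeat families named are up to 5 each way with the lowest adjusted p. The sex comparisons name the 2 largest ratios each way. Where a group has no count, the fold is a lower bound against 3 counts over the group. Binomial intervals are exact at 95% and, like these floors, cover counting error only.

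The pipeline was tested on simulated data drawn from the real means, dispersions and library sizes. In the comparison of ZZY10307 with JU1421, over 13289 genes, it recovered 11% of genes changed 2-fold and 49% of those changed 4-fold. For ZZY10330 against JU1421 these were 10% and 52%, for AF16 against JU1421 18% and 44%, and for ZZY10330 against ZZY10307 13% and 48%. Over 696 repeat families, 4-fold changes were recovered in 12.8%, 5.81% and 9.30% for ZZY10307, ZZY10330 and AF16 against JU1421. False calls were 4.76%, 3.125%, 3.125% and 8.96% of the calls in the 4 gene comparisons, in the order above, and 7.69%, 0% and 10% in the 3 comparisons of repeat families. The 8.96%, 7.69% and 10% lie above the 5% aimed at, though each rests on few calls. In these simulations, then, most 2-fold changes in single genes and most 4-fold changes in repeat families were missed. Only 200 of 13289 genes were changed there, which makes the adjusted p stricter than with the many changed genes of the real data. Recovery in the real comparisons is therefore not known from this: in ZZY10307 against JU1421, 3031 genes were called, of which 2427 differed by 2-fold or more. Why changes were missed was not tested. A simulated set shift of -0.5 was found by camera, and 4 of 100 random sets had p below 0.05.

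The choices above and the alternatives were fixed before the data were examined: DESeq2, RLE factors, total counts alone, TMM factors from genes without sex bias, no count filter, a 2-fold minimum, only the compared groups in the fit, a replicate block, sex-biased sets from JU1421, another minimum or fold for sex bias, and leaving out each library. Tests of the sets and of the repeat families between the sterile strains were added afterwards, as were the division of the JU1421 libraries between the comparisons, the repeat totals without the most abundant family and the exchange of whole strains. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.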

Results

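Messenger RNA of whole young adult worms was sequenced to compare sterile hybrid males with the fertile males of their parental species. JU1421 is a wild-type strain of Caenorhabditis nigoni, a nematode with separate males and females. AF16 is a wild-type strain of its close relative C. briggsae, in which animals with XX chromosomes are ordinarily self-fertile hermaphrodites. The introgression strains ZZY10307 and ZZY10330 are C. nigoni over most of the genome and carry a stretch of the C. briggsae X chromosome. In ZZY10307 it runs from 4.5 to 12.2 Mb, and in ZZY10330 from 16.4 Mb to the chromosome end. Males of both are sterile. Each of the 4 strains has 3 male libraries of 300 animals each, and JU1421 and AF16 have 1 female library each. Gene counts per library ranged from 2372653 to 3785106, with 12516 to 15231 of 23439 listed genes seen at least once. A second table of counts for 920 repeat families covered the 12 male libraries, with 112876 to 536392 counts each. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries.

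Males were first set beside females of the same strain, which describes the male and female transcriptomes against which the sterile males can be read. In AF16, 1800 genes were male-biased and 950 female-biased, at 4-fold or more and at least 5 CPM (counts scaled to a common library size) in the higher sex. In JU1421 the numbers were 2121 and 1040. Male bias was shared by 1361 genes and female bias by 557. WBGene00029072 stood at 4160 ± 275 CPM in AF16 males (SD, n = 3) and had no count in the AF16 female library, a ratio of at least 3851-fold against a floor of 3 counts. WBGene00025450 stood at 1910 ± 363 CPM in AF16 males and also had no female count, at least 1768-fold. On the female side, WBGene00035047 stood at 20390 CPM in the AF16 female library and 77.6 ± 16.4 CPM in the males, and WBGene00034456 at 170.3 CPM with no count in males, at least 535-fold. In JU1421, WBGene00031349 reached 9516 ± 306 CPM in males with no female count, at least 11484-fold. WBGene00031446 reached 9657 ± 990 CPM with 1 female count. WBGene00000365 stood at 2493 CPM in the JU1421 female library with no male count, at least 6919-fold, and WBGene00034777 at 4692 CPM against 0.879 ± 1.52 CPM in males. With 1 female library per strain, these ratios have no replicate check on the female side and carry no p-value. RNA amount and read length are given for the male libraries only. A difference in how male and female libraries were made therefore cannot be separated from sex, also in the classes used below.

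The genes male-biased in both strains were a larger part of the AF16 female library than of the JU1421 one. They took 1.99% of its gene counts (exact 95% binomial interval 1.98 to 2.01%) against 0.285% (0.279 to 0.291%) in the JU1421 female library. In males they took 28.8% in AF16 and 31.3% in JU1421. The intervals cover counting error only and compare 2 libraries, not the species. The sets defined in AF16 were used in all tests below, because AF16 libraries enter none of the comparisons of sterile males with JU1421.

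Sterile ZZY10307 males had low levels of male-biased genes. Male-biased genes took 11.8 ± 0.579% of gene counts in ZZY10307 (SD, n = 3) against 32.1 ± 1.65% in JU1421 and 31.02 ± 0.607% in AF16. Of 1779 male-biased genes tested, 1028 fell and 70 rose against JU1421, with a median log2 fold change of -1.45, while genes of neither class had a median of 0.20. Adjusted over the list alone, 1115 fell and 96 rose. The fall was steeper where male bias in AF16 was stronger: the median was -1.29 over the 1300 genes with 4- to 16-fold bias, -1.64 over 351 genes with 16- to 64-fold bias and -4.40 over 128 genes beyond 64-fold, of which 120 fell. These classes rest on the single AF16 female library, and AF16 animals with XX chromosomes are ordinarily self-fertile hermaphrodites. Of the genes male-biased in AF16, 232 had no count in that library. Of those male-biased in JU1421, 1074 had none in the JU1421 female library, and 766 lay beyond 64-fold. With the prior count of 2, only well expressed genes can lie beyond 64-fold. The classes may thus sort genes by abundance or by their level in the AF16 female library, not only by strength of male bias. Female-biased genes moved less and the other way, with 70 of 674 rising, 19 falling and a median of 0.39. Adjusted over the list alone, 53 rose and 16 fell. Their share of counts was 3.11 ± 0.299% against 2.19 ± 0.0716% in JU1421. The smaller male-biased share by itself raises the share of all other genes, and the median of genes of neither class, 0.20, also lay above 0. Part of this rise is therefore not particular to female-biased genes.

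**Figure D1:**
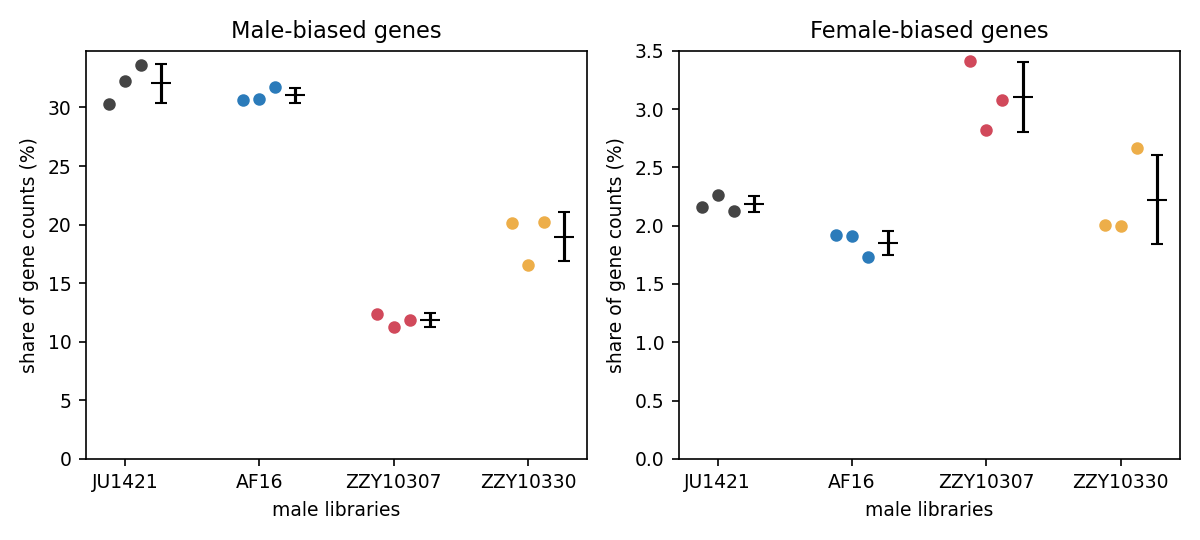
Share of gene counts, in percent, taken by male-biased genes (left) and female-biased genes (right) in each male library. Points are libraries, bars are mean ± SD of 3. The male-biased share lies between 11.3 and 12.4% in ZZY10307 and between 30.3 and 33.6% in JU1421.

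Across all 13289 tested genes, 3031 differed between ZZY10307 and JU1421, 1235 higher and 1796 lower. Male-biased genes made up 57.2% of those that fell, against 13.4% of all genes tested. Of single genes, WBGene00040934 stood at 168.7 ± 17.2 CPM in JU1421 males with no count in ZZY10307, at least 553-fold lower. WBGene00029353 fell from 535 ± 75.3 CPM to a single count, a ratio of 6109 with a counting interval of 945 to 208171. That count lies in ZZY10307 replicate 2, and without that library the fitted log2 fold change goes from -11.87 to -13.62, with no count left in the strain. Both were male-biased in JU1421 but stood at 2.74 and 1.90 CPM in AF16 males. In the other direction, WBGene00027595 had no count in JU1421 or AF16 males and stood at 47.2 ± 22.03 CPM in ZZY10307, at least 115-fold higher. WBGene00025461 had none in JU1421 males and stood at 43.4 ± 10.997 CPM, at least 106-fold higher. Separation of the 3 libraries of each strain was a condition for naming these 4, whose adjusted p ran from 9.50e-07 to 0.000388 (edgeR).

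By camera, a set test that compares a list with all other genes, the male-biased list was lower (adjusted p = 4.85e-41) and the female-biased list higher (adjusted p = 0.00377). With an estimated correlation between genes the first call held (adjusted p = 0.00478) and the second was lost (adjusted p = 0.0560 with an estimated correlation). The exact two-sided permutation test of the shares of counts gave p = 0.1 for both classes, the smallest that 3 against 3 libraries allow. Scaled by total counts alone, without TMM factors, the split became 2476 higher and 1242 lower, as the median of all genes moved from 0.09 to 0.48.

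ZZY10330 males, with a different part of the X chromosome from C. briggsae, also had low male-biased expression. Male-biased genes took 18.97 ± 2.11% of gene counts (SD, n = 3). Of the 1779 genes, 960 fell and 124 rose against JU1421, with a median log2 fold change of -1.18 against 0.12 in genes of neither class. Adjusted over the list alone, 1040 fell and 150 rose. Medians were -1.04, -1.36 and -2.58 in the 3 classes of rising male bias in AF16, with the limits given above. Of the 128 genes in the highest class, 113 fell. Female-biased genes went both ways, with 49 rising, 58 falling and 567 of 674 not passing the test. Their median was -0.23, and 0.00 when libraries were scaled by total counts alone. With sets from JU1421 it turned to 0.26 (adjusted p = 0.00330 by camera, the set test described above), but those sets were chosen with the control males and are not independent. Adjusted over the list alone, 42 rose and 44 fell. Their share of counts, 2.22 ± 0.385%, differed from the 2.19% of JU1421 by less than the spread between replicates. The smaller male-biased share by itself raises the others, so this does not show an unchanged level.

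**Figure D2:**
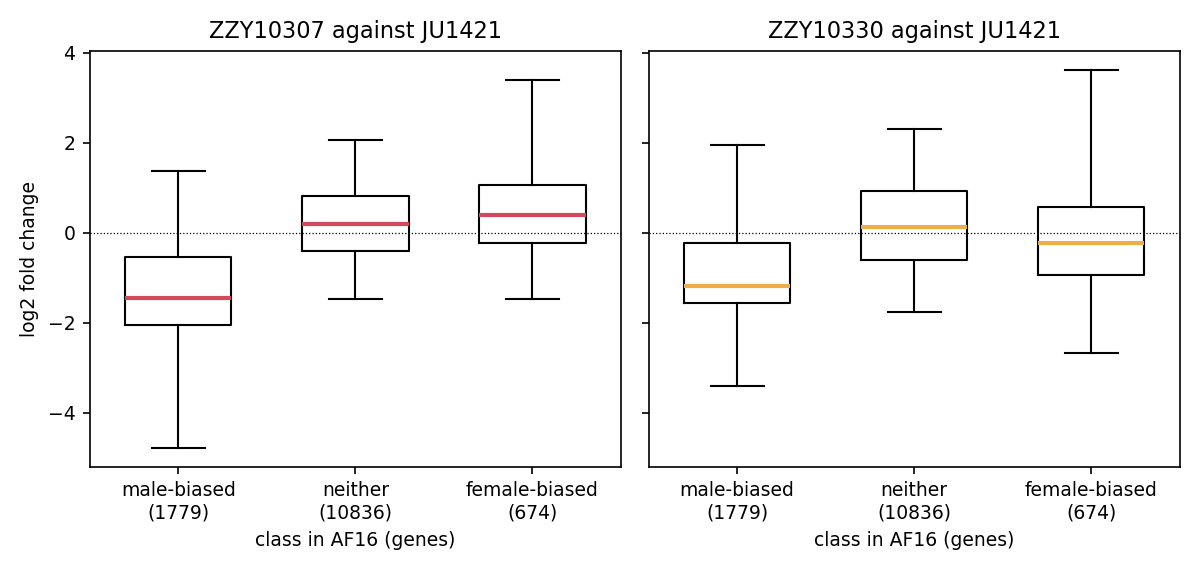
Log2 fold change against JU1421 of the tested genes, by sex class in AF16, in ZZY10307 (left) and ZZY10330 (right). Boxes span the quartiles with the median as a coloured line, and whiskers run from the 5th to the 95th percentile. The male-biased medians are -1.45 and -1.18, and the female-biased medians 0.39 and -0.23, the last of which is 0.00 under total counts alone and 0.26 with sets from JU1421.

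In all, 3803 genes differed between ZZY10330 and JU1421, 1670 higher and 2133 lower, and male-biased genes were 45.01% of those that fell. WBGene00034383, male-biased in both parents, stood at 47.2 ± 16.4 CPM in JU1421 and had no count in ZZY10330, at least 158-fold lower. WBGene00029391, also male-biased in both, stood at 21.1 ± 3.32 CPM in JU1421 and had no count either, at least 70.6-fold lower. In ZZY10307 males WBGene00034383 and WBGene00029391 were low too, at 0.973 and 3.40 CPM. WBGene00024230 had no count in JU1421 and stood at 37.0 ± 11.03 CPM in ZZY10330, at least 90.1-fold higher, and at 29.1 CPM in ZZY10307 and 28.7 CPM in AF16 males. WBGene00027417 rose from no count to 23.2 ± 24.8 CPM, at least 56.5-fold, but its libraries stood at 6.07, 11.8 and 51.6 CPM. Adjusted p of these 4 genes ran from 1.42e-07 to 0.000359 (edgeR).

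The male-biased list was lower by camera (adjusted p = 4.24e-19, and 0.0231 with an estimated correlation), and the female-biased list did not pass (adjusted p = 0.372), though it did with sets from JU1421, as given above. The exact two-sided permutation test of the male-biased share gave p = 0.1, the smallest possible, and that of the female-biased share p = 1. Scaled by total counts alone, the split became 2234 higher and 1570 lower.

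The strains differed from each other in a direct comparison. Male-biased genes stood higher in ZZY10330 than in ZZY10307, with 270 of 1779 higher, 16 lower and a median difference of 0.42 on the log2 scale. Female-biased genes stood lower, with 52 of 674 lower, 22 higher and a median of -0.54. Adjusted over the lists alone, 352 male-biased genes were higher and 24 lower, and 62 female-biased genes lower and 23 higher. In the 128 genes beyond 64-fold male bias the median difference was 1.64, with 63 higher and 2 lower. Over all genes 1131 differed, 674 higher and 457 lower in ZZY10330. WBGene00030262 stood at 924 ± 237 CPM in ZZY10330 and 1.52 ± 2.202 CPM in ZZY10307, a 606-fold difference (log2 9.20, SE 0.54, edgeR adjusted p = 3.46e-08; log2 11.39 without ZZY10307 replicate 1), and WBGene00030261 at 2792 ± 357 against 13.4 ± 6.20 CPM, a 208-fold difference (log2 7.72, SE 0.34, adjusted p = 1.46e-12). Both were at AF16-like levels in ZZY10330, since AF16 males had 693 and 2052 CPM while JU1421 males had 6.32 and 6.85 CPM. WBGene00035810 had no count in ZZY10330 and 16.2 ± 4.56 CPM in ZZY10307, at least 54.4-fold lower, and WBGene00033489 none against 14.7 ± 9.77 CPM, at least 49.3-fold lower, a call lost without ZZY10307 replicate 1 (adjusted p = 0.0924).

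Both set differences passed camera (adjusted p = 1.77e-10 and 6.59e-08) and held with an estimated correlation (adjusted p = 0.0471 and 0.00473). These set tests of the difference were chosen after seeing the data. The count of differing genes rests partly on single ZZY10307 libraries: it was 662 without replicate 2 and 582 without replicate 3. Scaled by total counts alone, the split became 502 higher and 746 lower in ZZY10330.

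**Figure D3:**
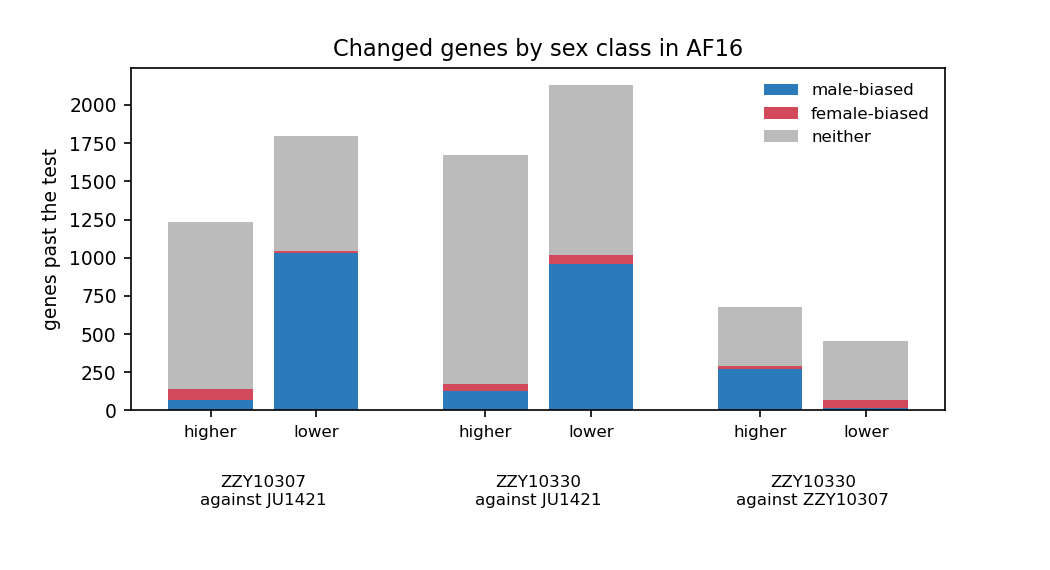
Number of genes past the test (edgeR, adjusted p below 0.05) in each comparison of male libraries, by direction and by sex class in AF16. Of the genes lower than in JU1421, 1028 of 1796 in ZZY10307 and 960 of 2133 in ZZY10330 are male-biased, a split of directions that depends on the TMM factors.

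The fertile parents themselves differed in 2718 genes, 1226 higher and 1492 lower in AF16 than in JU1421 males. Male-biased genes went both ways: 313 of 1779 were higher and 230 lower, with a median of 0.15, and their share of counts differed by less than the spread between replicates (exact two-sided permutation p = 0.4). Because these genes were chosen on the AF16 males, that count is not independent evidence. WBGene00029533 stood at 174.4 ± 28.4 CPM in AF16 males (SD, n = 3) with no count in JU1421 males, at least 425-fold higher. WBGene00000365, the female-biased gene named above, stood at 159.6 ± 68.1 CPM in AF16 males and had no count in JU1421 males, at least 389-fold higher. WBGene00086925 and WBGene00030296 had no count in AF16 and stood at 344.5 ± 90.6 and 157.1 ± 45.3 CPM in JU1421, at least 1015-fold and 463-fold lower. Adjusted p of these 4 genes ran from 7.95e-12 to 0.00127 (edgeR). Reads of either species may be assigned unequally to a shared gene list, and the reference used for counting is not given in the sources used here, so a species difference in counts can hold a difference in assignment.

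Many genes in sterile males lay outside the range of both parents. In ZZY10307, 1606 genes differed from JU1421 and from AF16 in the same direction, 467 above both and 1139 below both, and 849 of those below were male-biased. In ZZY10330 there were 1780 such genes, 709 above and 1071 below, with 666 of those below male-biased. Below both parents in both strains were 721 genes, 601 of them male-biased, and 260 genes were above both parents in both strains. The male-biased genes were chosen for being high in AF16 males, which favours their falling below AF16, so their shares here are not independent evidence. Fertile strains put in the same role also gave many genes: JU1421 lay outside AF16 and ZZY10307 in 1013 genes and outside AF16 and ZZY10330 in 1229, and AF16 outside JU1421 and these strains in 1385 and 1266. Under total counts alone the splits became 1138 above and 794 below in ZZY10307, and 1014 above and 783 below in ZZY10330.

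The lists of changed genes overlapped between the sterile strains. Against JU1421, 848 genes were higher in both and 1359 lower in both, of which 879 were male-biased, and 16 genes changed in opposite directions. Independent lists of these lengths would share 155 and 288 genes. Since both comparisons use the same JU1421 libraries, unchanged groups were simulated against them: 50 simulations shared 0 genes on average. They called only 0.06 genes per comparison, so this 0 does not show how many of the shared genes come from the common controls. Across the 13094 genes with a JU1421 count, the log2 fold changes correlated at 0.667 against 0.520 in simulations, with a covariance of 1.36 against 0.346, a difference of 1.01. Genes are not independent replicates, and 3 control libraries are too few to leave 2 for each comparison, so part of the excess may come from the shared controls. In a check added after seeing the data, 1 JU1421 library served one strain and the other 2 the other. Over the 6 such divisions, 315 to 418 genes were higher in both and 690 to 944 lower in both, where independent lists would share 50.1 to 64.8 and 111 to 162. The covariance was then 1.18 to 1.29. Under total counts alone, 1570 genes were higher in both and 945 lower in both.

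Repeat families are known only by number, and one of them, cb_rnd-5_family-688, held most of the fall in repeat counts in sterile males. As CPM of raw gene counts, without TMM factors, all families summed to 165298 ± 16048 in JU1421, 103567 ± 4996 in AF16, 47897 ± 6959 in ZZY10307 and 86778 ± 19226 in ZZY10330 (SD, n = 3). On the same scale cb_rnd-5_family-688 alone stood at 130530, 72521, 18987 and 49531, on average 78.9% of all repeat counts in JU1421 and 39.5% in ZZY10307. Without it, in a sum added after seeing the data, the totals were 34768 ± 3141 in JU1421, 31046 ± 2851 in AF16, 28909 ± 3663 in ZZY10307 and 37247 ± 5606 in ZZY10330. The exact two-sided permutation test against JU1421 gave p = 0.2 and 0.7 for the sterile strains. As it cannot go below 0.1, a change in the remaining families is not excluded. In CPM with TMM factors, used for all single families here, it fell from 149358 ± 24156 CPM in JU1421 to 16488 ± 3287 CPM in ZZY10307 (log2 fold change -3.18, SE 0.24, edgeR adjusted p = 5.83e-37) and to 48473 ± 16905 CPM in ZZY10330 (-1.62, SE 0.23, adjusted p = 1.11e-10). AF16 males had 77180 ± 3535 CPM of it. The exact two-sided permutation test of the totals over all families gave p = 0.1, the smallest possible, for each sterile strain against JU1421.

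**Figure D4:**
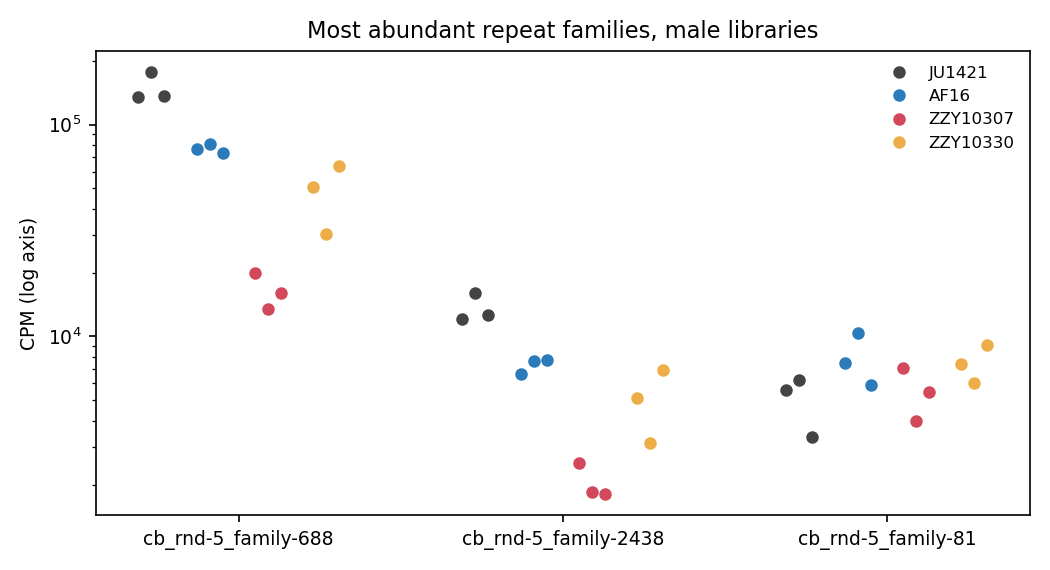
CPM, with TMM factors, on a log axis of the 3 most abundant repeat families in each male library, with a point per library. Means of cb_rnd-5_family-688 run from 16488 CPM in ZZY10307 to 149358 CPM in JU1421, while cb_rnd-5_family-81 lies between 3358 and 10371 CPM in all 12 libraries.

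Of 696 families tested, 25 differed between ZZY10307 and JU1421, 7 higher and 18 lower, and 38 between ZZY10330 and JU1421, 14 higher and 24 lower. DESeq2 called 34 in ZZY10307, 16 higher and 18 lower, so the excess of lower families there depends on the tool. The median log2 fold changes over all 696 were 0.11 and 0.01. In both strains c_sp9_rnd-4_family-2009 fell, from 1454 ± 153 CPM to 72.3 ± 14.4 CPM in ZZY10307 (-4.33) and 99.5 ± 24.98 CPM in ZZY10330 (-3.87). So did c_sp9_rnd-5_family-9330, from 171 ± 41.8 to 7.54 ± 3.04 and 25.5 ± 8.54 CPM, and cb_rnd-5_family-2438, from 13599 ± 2123 to 2061 ± 409 and 5058 ± 1895 CPM. The family c_sp9_rnd-5_family-3359 likewise fell in both, from 2016 ± 351 to 466 ± 37.7 and 868 ± 242 CPM, and in ZZY10330 c_sp9_rnd-5_family-2851 fell from 244 ± 77.5 to 63.7 ± 16.3 CPM. AF16 males had 493, 358, 7348, 259 and 199 CPM of these falling families, in the order named. Only c_sp9_rnd-5_family-3359 stayed between the means of the parents. Higher in both were cb_rnd-5_family-4518, from 717 ± 273 to 2018 ± 285 and 2805 ± 303 CPM, and c_sp9_rnd-5_family-2147, from 24.6 ± 5.56 to 108 ± 20.3 and 120 ± 31.8 CPM. AF16 males had 3240 CPM of the former and 11.3 CPM of the latter, so the former rose toward the AF16 level and the latter above both parents. Further rises in ZZY10307 were c_sp9_rnd-5_family-6939 to 384 ± 90.4 CPM, c_sp9_rnd-5_family-1398 to 58.7 ± 26.1 CPM and cb_rnd-3_family-789 to 11.6 ± 2.87 CPM. AF16 males had 41.7, 0.654 and 23.5 CPM of these, so only cb_rnd-3_family-789 rose toward the AF16 level. The call of c_sp9_rnd-5_family-1398 was lost without ZZY10307 replicate 1 (adjusted p = 0.0634), and that of cb_rnd-3_family-789 without JU1421 replicate 2 or 3 (adjusted p = 0.0750 and 0.101). In ZZY10330, cb_rnd-5_family-3381 rose to 3446 ± 2666, cb_rnd-5_family-4471 to 4021 ± 983 and c_sp9_rnd-5_family-81 to 346 ± 49.4 CPM, against 791, 1225 and 2.86 CPM in AF16 males. The first of these stood at 1837, 1978 and 6523 CPM in its 3 libraries, and its log2 fold change of 2.73 was 1.88 without ZZY10330 replicate 3. Shared between the lists were 2 higher and 13 lower families, where independent lists would share 0.141 and 0.621. Both lists use the same JU1421 libraries, and 50 simulations of unchanged groups against them shared 0 families but called only 0.05 per comparison. With JU1421 divided as above, 0 to 2 higher and 5 to 9 lower families were shared, where independent lists would share 0.253 to 0.427 lower ones. The ZZY10307 count was 16 without ZZY10307 replicate 3, and the ZZY10330 count was 24 without JU1421 replicate 1 and 22 without replicate 3.

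Between the parents 144 families differed, and the direction followed the species prefix of the family's name. Of the families higher in AF16, 41 carry the prefix cb and 9 the prefix c_sp9, while of those lower 9 carry cb and 85 c_sp9. The median log2 fold change was 1.56 over 276 cb families and -1.26 over 420 c_sp9 families. Examples are cb_rnd-5_family-6811 at 62.3 ± 12.7 CPM in AF16 with no count in JU1421, at least 152-fold higher, and c_sp9_rnd-5_family-192 at 555 ± 103 CPM in JU1421 with 1 count in AF16 (log2 -11.80, or -13.73 without AF16 replicate 3, which holds that count). The latter kept 442 CPM in ZZY10307 and 472 CPM in ZZY10330. Directly between the sterile strains 18 families differed, 9 each way, in a test chosen after seeing the data. That count was 10 without ZZY10307 replicate 1 and 9 without replicate 3.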

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

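The tests for females among the picked animals and all set and repeat tests between the sterile strains were chosen after the results were seen. The results in this paragraph and the next were singled out because ZZY10330 and ZZY10307 differed in a direct test. Of the patterns discussed after them, the second starts from that test and the third uses it in part. Male-biased genes were higher in ZZY10330 by a median of 0.42 on the log2 scale, female-biased genes lower by a median of -0.54, and 1131 genes and 18 repeat families differed. Without ZZY10307 replicate 3 these counts were 582 and 9. For the 6 libraries of that comparison only 10 splits exist, too few for a share under 0.05: the real split, 1 of 10, gave 1131 genes and the highest other 1 gene.

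Among genes named against JU1421, WBGene00027595 was lower in ZZY10330 than in ZZY10307 (log2 -8.39), as were WBGene00025461 (-1.80), WBGene00034383 (-4.65) and WBGene00029391 (-6.37). WBGene00034383 and WBGene00029391 had no count in ZZY10330 and WBGene00027595 stood there at 0.0920 CPM, so their fitted values are no bounds. WBGene00034383 and WBGene00029391 were also low in ZZY10307, at 0.973 and 3.40 CPM against 47.2 and 21.1 CPM in JU1421. Their difference between the sterile strains is thus one between low levels. Among repeat families, cb_rnd-5_family-688 was higher in ZZY10330 (1.56), as were c_sp9_rnd-5_family-9330 (1.76), cb_rnd-5_family-2438 (1.30), c_sp9_rnd-5_family-3359 (0.90), cb_rnd-5_family-3381 (2.74, but 1.88 without ZZY10330 replicate 3), cb_rnd-5_family-4471 (1.66) and c_sp9_rnd-5_family-81 (1.14). Lower in ZZY10330 were cb_rnd-3_family-789 (-4.76, or -8.11 and -4.14 without ZZY10330 replicate 1 or 2) and c_sp9_rnd-5_family-2851 (-2.21).

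The first pattern is the low level of male-biased genes in both sterile strains. To dilute the male-biased share that far, females picked by mistake would have to supply 64.4% of ZZY10307 and 41.7% of ZZY10330 gene counts. The share of animals this takes is not known, since RNA per animal is not given. But across the 20 most abundant female-biased genes of the JU1421 female library the level was mostly lower. Their 75th percentile was 12.9% of the female level in ZZY10307 and 4.51% in ZZY10330. Scaling is argued against by the medians under total counts alone, the nearer to 0 being -0.95. Over the 639 male-biased genes that differ by under 0.5 log2 between the parents, the medians were -1.49 and -1.19. For these genes this argues against unequal counting of C. briggsae sequence. An unequal assignment of reads offset by a difference in expression would go unseen. Which of these genes lie in the X intervals is not known, and most of the genome of both strains is C. nigoni. What stays open was not tested. The strains differ in fertility and in genotype, and the introgression males came from a cross and were picked by a fluorescent marker. Other differences in how the animals were obtained and handled were not checked. Whole animals also cannot separate a smaller male germline from lower expression within it.

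The second pattern is the lower level of female-biased genes in ZZY10330 than in ZZY10307. Over the 20 genes the ZZY10307 median was 3.54% of the female level, against 1.76% in ZZY10330, 1.36% in JU1421 and 5.91% in AF16 males, and by itself this median would leave a few females possible. Whole females would bring their most abundant transcripts too, yet the 3 most abundant stood at no more than 0.0166% of the female level in ZZY10307, where the pattern would need 6.102%. This second reading was added after the first was seen. If a smaller male share raised all other genes alike, female-biased genes would move with genes of neither class. Their median lay -0.52 from that of genes of neither class (95% resampling interval over genes, which are not independent, -0.62 to -0.42). This argues only against an equal rise of both classes. Genes of neither class can have male bias under 4-fold, and genes at 4- to 16-fold bias differed by a median of 0.37. A male share that moves the 2 classes unequally thus stays open, as does a difference in genotype between the strains. Female-type expression within ZZY10307 males also stays open and was not tested.

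The third pattern concerns genes near 0 in JU1421 males (under 1 CPM) and present in AF16 males (10 CPM or more). Of 92 such genes, 10 appeared in ZZY10307 and 13 in ZZY10330 at no less than the AF16 level divided by 4. If these were C. briggsae alleles carried in the labelled X intervals, the lists should differ, since the X intervals differ, but 9 genes were in both, 90% of the shorter list, where independent lists would share 1.41. Over the 27 choices of these limits tried, this one included, the shared part was 73.3 to 100%. These choices overlap, and some lists hold only 2 genes. Both lists use the same JU1421 libraries for the limit and for the call, which by itself favours sharing. The 1.41 is therefore not a fair expectation. The sharing bears only on the lists as a whole. A looser limit, added after these were seen, took the 214 genes called at least 8-fold higher in AF16 than in JU1421 males, at 10 CPM or more in AF16. Of these, 31 appeared in ZZY10307, 55 in ZZY10330 and 26 in both, and 19 appeared in ZZY10330 alone with a higher level in the direct test, against 0 in ZZY10307 alone. The genes WBGene00030262 and WBGene00030261, above the limit in JU1421 (6.32 and 6.85 CPM), are AF16-like in ZZY10330 only (924 and 2792 CPM). For genes found in ZZY10330 alone, carried alleles stay open. The lists are short, and what both strains share beside the interval, such as the marker, the crossing scheme and sterility, cannot be separated here.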

How the results depend on the processing

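Under the alternatives, 237 values of main results kept their side of the threshold or stayed within 1.5 times, 12 counts moved further, 2 medians reversed and 1 list lost its call. Named genes and families kept direction and call in 638 of 648 values, 10 lost the call, each on leaving out 1 library, and 0 reversed. The male-biased medians against JU1421 ranged over all alternatives from -1.52 to -1.06 in ZZY10307 and from -1.27 to -0.95 in ZZY10330. The female-biased list of ZZY10307, at 0.39, lost its call with an estimated correlation (adjusted p = 0.0560; range over its alternatives 5.02e-14 to 0.0560). That of ZZY10330, not called at -0.23, went to 0.00 under total counts alone and reversed to 0.26 with sets from JU1421 (adjusted p = 0.00330; range 0.00330 to 0.724), but those sets were chosen with the control males and are not independent. Total counts alone moved the median of all genes to 0.48, 0.20 and -0.13 in ZZY10307 against JU1421, ZZY10330 against JU1421 and ZZY10330 against ZZY10307. With a 2-fold minimum, sex bias covered 3295 and 2726 genes in JU1421 (male, female) and 2837 and 2612 in AF16, since fewer genes are excluded. Leaving out 1 library in turn gave 582 to 1159 differing genes between ZZY10330 and ZZY10307 (662 without ZZY10307 replicate 2, 582 without replicate 3). For repeat families it gave 16 to 21 in ZZY10307 (16 without its replicate 3), 22 to 41 in ZZY10330 (24 without JU1421 replicate 1, 22 without replicate 3) and 9 to 18 between the sterile strains (10 without ZZY10307 replicate 1, 9 without replicate 3). DESeq2 called 34 families in ZZY10307, 16 higher and 18 lower. Replicate numbers do not pair the samples: 18 correlations of same-numbered libraries ran from -0.0468 to 0.0359. With the number as a replicate block, repeat families in ZZY10330 went from 38 to 24, 6 higher and 18 lower, and genes from 3031 to 2882, 3803 to 3590, 2718 to 2507 and 1131 to 913 in ZZY10307, ZZY10330 and AF16 against JU1421 and between the sterile strains. The cause of these moves was not tested. The alternatives listed beforehand for functional gene lists and for genes of the X intervals were not run, because no names or positions were used here.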

Other observations

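The test on traces in the AF16 female library was chosen after the results were seen, and it does not stand apart from the strength of male bias. Of the 1779 male-biased genes tested, 354 have no more than 1 count in that library. In ZZY10307 these had a median log2 fold change of -2.23 against JU1421, and the 1425 genes with a trace -1.39, a difference of -0.84 (95% resampling interval over genes -1.60 to -0.47). In ZZY10330 the medians were -1.67 and -1.13, a difference of -0.54 (-0.75 to -0.31). The share of genes called lower went the other way, 52.3% without and 59.2% with a trace in ZZY10307, and 47.5% and 55.6% in ZZY10330. At 50 CPM or more in AF16 males it did not, with 93.6% and 83.1% in ZZY10307 and 87.3% and 78.6% in ZZY10330. Among genes that differ by under 1 log2 between the parents, added afterwards, the difference was -0.57 in ZZY10307 (-1.08 to -0.01) and -0.48 in ZZY10330 (-0.72 to -0.20). The fall was thus not even over male-biased genes, as their classes of bias also show. Abundant genes without a trace are by construction strongly male-biased: of 110 such genes at 50 CPM or more in AF16 males, 108 lie beyond 64-fold. Within classes of bias, also added, the difference changed sign. It was 0.52 in ZZY10307 and 0.43 in ZZY10330 at 4- to 16-fold bias, -0.31 in both at 16- to 64-fold, and -0.61 and -0.80 beyond 64-fold, where only 16 genes have a trace. Whether a trace matters beside the strength of bias stays open.

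Whether an arbitrary grouping of libraries gives such results was checked by refitting other splits. With 10 splits per comparison of 3 against 3, no share under 0.05 can be reached, and the real split ranked 1 in each. It gave 3031 genes and 25 repeat families in ZZY10307, where the highest other gave 0 and 0, 3803 and 38 in ZZY10330 against 1 and 0, and 2718 and 144 in AF16 against 0 and 0. The absolute medians were 1.45 and 0.39 for male- and female-biased genes in ZZY10307 against 0.55 and 0.20, and 1.18 and 0.23 in ZZY10330 against 0.49 and 0.17. For genes outside both parents, 100 groupings of 9 libraries were fitted per strain, the real one included. Only the real one reached the 1606 of ZZY10307 (highest other 0), and only the real one the 1780 of ZZY10330. The highest other there was 1229, from the regrouping that exchanges the 3 strains whole, with JU1421 in the place of ZZY10330, which is structure of the samples. For the 2207 shared genes, too, only the real one of 100 groupings was as large, and the highest other was 46. The real grouping thus lies within 0.05 for these 3 results, but regroupings that mix strains call few genes by construction, so the ranks show only that the strains differ from each other. No whole exchange was drawn for ZZY10307. Exchanges of whole strains, added afterwards, gave 1013 and 1385 genes with JU1421 or AF16 in the place of ZZY10307, and 1229 and 1266 in that of ZZY10330. With ZZY10307 or ZZY10330 as the common control, 487 and 492 genes were shared.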
